A study of Mus musculus with 36 samples.

How the data were processed

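RNA from the peripheral blood of 18 male mice was measured on 36 Affymetrix arrays. The mice came from 6 inbred strains (A/J, C3H/HeJ, C57Bl/6J, DBA/2J, FVB/NJ and 129S1/ImJ), 3 mice per strain. Per the labels' protocols, blood was drawn from the heart into EDTA and Trizol, total RNA was extracted, and a portion of each extract went through the GLOBINclear kit, which removes alpha and beta globin mRNA with capture oligonucleotides. Each mouse thus gave 1 array of whole RNA and 1 of GLOBINclear RNA. The labels' protocol text writes the last of these as 129S1/SvImJ, while the strain label reads 129S1/ImJ, which is used here. Samples were grouped by preparation and strain from their titles, and replicate numbers were taken from the same titles.

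The deposited values were log2 expression summaries, 1 per probe set and array, for 45101 probe sets. That they are on a log2 scale was read from the values. Per the submitters' processing notes, GCRMA, MAS5 and the affy package were used, with no version, role or order. Whether the arrays of both preparations were normalized together is not given in the sources used here. The arrays of the preparations differed in distribution (95th percentile 5.22 in whole and 6.57 in GLOBINclear RNA), so the deposited values had not been forced to 1 distribution over all arrays. Hybridization day, scanner and kit run are not given in the sources used here. A probe set at the bottom of the scale carries background, and a change there is compressed, as it can be near the top of the scale. The number of arrays limits the precision, and 3 mice per strain limit it for comparisons of strains and for effects within a strain.

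The 64 control probe sets were set aside and used only for quality measures. The others were tested if their mean over all 36 arrays was above the median of those means (log2 2.89), which left 22518 probe sets. Probe sets were named through the platform's annotation. Outside the controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and no gene was named from a probe set with several or no symbols except the globin sets, whose symbols all belong to adult globin genes. Through Entrez numbers 34754 probe sets were matched to a current gene table, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, of which 11353 were tested. All value columns were used (0 left unused), and no array was left out.

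Fits were made with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with eBayes and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with 0.05 as the threshold. The globin reduction effect (GLOBINclear minus whole) was fitted with the mouse as a block, once with 1 effect for all strains and once with an effect per strain, whose differences gave the interaction. Strain differences were tested in each preparation alone by limma's F test over the 6 strains, and each strain was set against the mean of the other 5 on the average of each mouse's 2 arrays. Quality measures were compared over the 18 pairs by a two-sided permutation test that flipped the sign of each pair's difference at random (100000 flips, smallest possible p 1e-05). They formed a family of 11. The count of strain-variable probe sets was compared between preparations with 99 random swaps of the preparation within mice (smallest possible p 0.01), and the spread within strains with 1000 permutations (smallest possible p 0.001). Gene lists were tested with camera, limma's competitive set test, at its preset correlation of 0.01 and again with an estimated correlation. Figures were drawn in python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.

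Before the data were examined, the designs, 22 gene lists, the main alternatives and the rule for named genes were fixed. The lists were adult globins, embryonic globins, heme synthesis, erythrocyte membrane and cytoskeleton, other erythroid genes, T cell markers, B cell markers, NK and cytotoxic cell markers, neutrophil markers, monocyte and macrophage markers, platelet and megakaryocyte markers, eosinophil, basophil and mast cell markers, MHC class II, MHC class I and peptide loading, interferon-stimulated genes, immediate early and stress response genes, cytosolic ribosomal proteins, oxidative phosphorylation, proteasome, splicing and nuclear RNA binding, zinc finger (Zfp) genes taken to stand for GC-rich or short-lived transcripts, and genes with known strain alleles. The rule named the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold and moved the same way in all 18 mice. It added up to 3 members per list by the size of the moderated statistic, the 6 genes with the smallest interaction p, and, for each strain, 3 genes that stood highest and 2 that stood lowest. It also took members of the strain allele list that passed in both preparations, and 4 genes per preparation whose strain differences passed in that preparation and had an unadjusted p over 0.5 in the other. Clone and model names were passed over. Other list members and the other probe sets of named genes were chosen after their values were seen.

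Mice paired the arrays by design. As a check, the deviations of each array from its strain mean were correlated between preparations over probe sets. Arrays of the same mouse correlated at 0.162 to 0.664 in 17 of 18 mice and matched better than any other mouse of the strain. The exception was DBA/2J replicate 3 (-0.0783).

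The fits were tested on simulated data of 22518 probe sets, with 67 changed by log2 0.5, 67 by log2 1 and 66 by log2 2. For globin reduction over all strains 94.0, 100 and 100% were recovered, with 6.22% of calls false. For globin reduction in 1 strain the values were 40.3, 74.6 and 100% (7.74% false), for the interaction 19.4, 49.3 and 87.9% (4.59% false), for strain differences in whole RNA 28.4, 62.7 and 86.4% (4.84% false), in GLOBINclear RNA 31.3, 62.7 and 89.4% (5.43% false), and for 1 strain against the other 5 they were 55.2, 89.6 and 98.5% (5.81% false). With 1 of the 22 lists raised, camera called that list (adjusted p = 9.02e-181) and 0 of the others. Probe sets were simulated independently of each other, so this could not show false list calls that come from correlated genes.

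Alternatives covered the scaling (array medians, quantile normalization over all arrays or within each preparation, and centring on the hybridization spike-ins), the filter (none, or a mean above the 75th percentile), the block (none, random), the trend, array weights, stricter thresholds, each mouse and each strain left out in turn, the mean of all probe sets of a gene, and the correlation in camera. Choices made after seeing the data were a filter at a mean of log2 5, globin probe sets with a mean of at least log2 8 alone, the spread among probe sets with a mean of at least log2 7, and 2 mice left out together. A pseudocount had been foreseen for linear values and had no use on the log2 scale. How a changed list call was defined was revised after the alternatives had first been computed, so that direction follows the list's median and a call counts as held when camera passes in the same direction. Which list results of single strains are printed was also settled after they were seen, and all that passed are given. After spike-in centring, the globin signal and single genes are given relative to the shift of all probe sets.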

Results

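Gene expression was measured in the peripheral blood of 18 male mice, 3 from each of the inbred strains A/J, C3H/HeJ, C57Bl/6J, DBA/2J, FVB/NJ and 129S1/ImJ. Each mouse gave a pair of arrays, 1 hybridized with whole blood RNA and 1 with RNA of the same extract after alpha and beta globin mRNA had been depleted (GLOBINclear). Globin transcripts make up most of the mRNA of red cells and reticulocytes, and the study set out to learn how they affect array measurements of blood. Values are log2 expression summaries as deposited, in 12 groups of 3 arrays. On the scale of these summaries 2495 ± 209 (SD, n = 18) probe sets reached log2 5 on an array of whole RNA (range 2196 to 3122) and 4364 ± 356 on an array of GLOBINclear RNA (range 3802 to 5278). Arrays of the same group correlated at 0.918 or above. The lowest values belonged to C57Bl/6J replicate 1 (0.918 in GLOBINclear RNA and 0.933 in whole RNA) and to 129S1/ImJ replicate 3 (0.948 in whole RNA).

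The first question was whether the kit removed its targets and what else moved on the array. Every tested adult globin probe set fell, among them an Hbb-b2 set from 11.04 ± 0.98 (SD, n = 18) to 7.57 ± 0.98, a log2 change of -3.47 ± 0.12 (SE). The probe set shared by the adult beta globin genes went from 14.3 to 12.9 (-1.40 ± 0.14, SD of the 18 differences), and those shared by Hba-a1 and Hba-a2 changed by -1.46, -1.03 and -1.0. These shared sets stood at 14.3 to 14.7 in whole RNA, close to the highest values of those arrays (14.64 to 15.63), so their changes are not comparable in size with those of dimmer sets. A set specific to Hba-a2 went from 5.85 to 4.91 and fell in 17 of 18 mice, while the second Hbb-b2 set, near background, changed by -0.12. All 7 had a limma adjusted p under the threshold, the weakest being that of Hba-a2 (adjusted p = 1.01e-05). In every mouse the mean over the adult globin sets dropped, from 10.1 ± 0.161 to 8.92 ± 0.212 (permutation p = 2e-05). The globin sets that remained were still among the brightest, at 12.2 on average for the 5 with a mean of at least log2 8, against 13.8 in whole RNA.

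Other control measures moved in all 18 pairs as well, each with a permutation p of 2e-05 and the same value after adjustment over the family of 11. The 3' minus 5' difference of the beta-actin and Gapdh control probe sets, a sign of shortened or partly copied RNA when high, rose from 0.130 ± 0.184 (SD, n = 18) to 1.17 ± 0.198. The 18S rRNA sets fell by 0.92. The poly-A spike-ins, added to the RNA before labelling, rose by 1.70, whereas the hybridization spike-ins, added after labelling, fell by 2.08. Single hybridization spike-in sets changed by -2.82 to -0.86. The cre sets, at 14.1 to 14.9 in whole RNA, changed by -1.31 to -0.86, and a bioD set at 14.1 by -1.72. The shared globin sets, at like levels, changed by -1.46 to -1.0, which cannot be told apart from a change of scale there. The bright Hbb-b2 set (-3.47) fell more than any of these spike-in sets. The median of all probe sets changed by -0.08 and the 95th percentile by 1.35. Centring the arrays on the hybridization spike-ins would thus shift all changes upward by 2.08, and the globin signal itself then stood 0.887 higher in GLOBINclear RNA. Relative to that shift its change was again -1.19, since the same shift is taken off. The changes of gene groups below are given on the deposited scale, which is the same as relative to the shift.

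**Figure D1:**
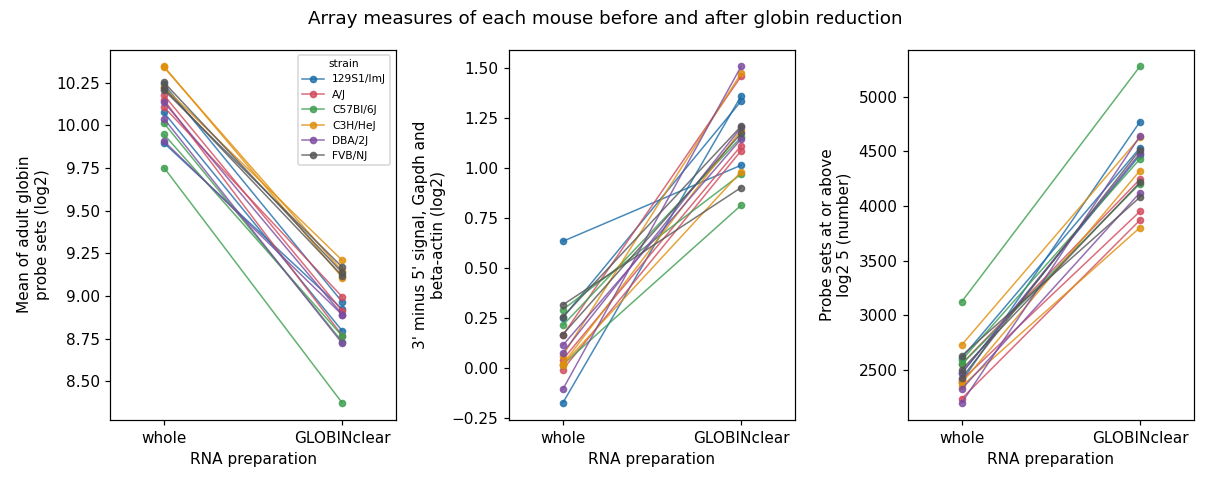
Array measures of each of the 18 mice in whole and in GLOBINclear RNA, 1 line per mouse, coloured by strain, with the RNA preparation on the x axis and the measure on the y axis (log2 signal, log2 difference or number of probe sets). In every mouse the adult globin signal fell (10.1 to 8.92 on average, although it stands 0.887 higher when arrays are centred on the hybridization spike-ins), while the 3' minus 5' difference (0.130 to 1.17) and the number of probe sets at log2 5 or above (2495 to 4364) rose.

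Genes gained signal after globin depletion far more often than they lost it when the change was large. Ptpa, an activator of protein phosphatase 2A, rose most, from 4.66 to 8.78 (log2 change 4.12 ± 0.12 (SE), 18 of 18 mice, limma adjusted p = 8.8e-16). It was followed by Ppp2r1a, the scaffold subunit of that phosphatase (3.55 ± 0.14), Scand1 (3.51 ± 0.12), Cgrrf1 (3.44 ± 0.17), Clns1a (3.40 ± 0.12), Tbc1d10b (3.30 ± 0.14), the seipin gene Bscl2 (3.29 ± 0.08), the focal adhesion gene Pxn (3.19 ± 0.12), the helicase subunit Mcm7 (3.15 ± 0.11), the complex I subunit Ndufb7 (3.15 ± 0.14), Ubr4 (3.13 ± 0.10) and Itgb5 (3.13 ± 0.14). In whole RNA several of these genes started near the floor, among them Scand1 and Clns1a (mean over all arrays 4.04 each) and Ubr4 (4.34). Their rises are lower bounds, and the order of the genes is not fixed. Losses beyond the globins were steep in a few probe sets. Armc8 fell from 13.1 to 7.32 (-5.80 ± 0.21) and Cpe, which encodes carboxypeptidase E, from 7.33 to 2.38 (-4.95 ± 0.20). After depletion Cpe stood at 2.37 to 2.40 in every strain, near the floor of the arrays, so that its change is a lower bound and its rank is not fixed. Susd5 (-3.21 ± 0.26), Gpaa1 (-3.12 ± 0.11), the noncoding RNA Meg3 (-2.78 ± 0.08), Unc45a (-2.70 ± 0.14), Iglon5 (-2.69 ± 0.18), Zfp420 (-2.35 ± 0.14), Slk (-2.11 ± 0.16), Mex3a (-2.09 ± 0.13) and Nrip2 (-2.02 ± 0.12) fell too, all in 18 of 18 mice. Of these Iglon5 (2.70), Slk (3.22), Mex3a (3.28) and Susd5 (3.43) also ended near the floor.

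Other tested probe sets of these genes often did not follow. Those of Ptpa changed by 0.51 and 2.44, those of Ppp2r1a by 0.43 to 3.31 and those of Itgb5 by 1.72 to 2.37. That of Ndufb7 changed by 2.01, that of Clns1a by 0.82 and that of Pxn by 0.39. Those of Mcm7 changed by 0.25 to 0.75 and that of Cgrrf1, near the floor, by 0.02. Such rises thus hold for the probe set named and not always for the gene. Whether probes that also bind other sequence played a part in the rises was not tested. The other tested Armc8 sets changed by -0.20, -0.19 and 0.09, that of Cpe by 0.34, that of Susd5 by -0.31, those of Unc45a by -0.69 and -0.05, and those of Slk by -0.21, 0.01 and 0.13. The other tested sets of Meg3 changed by -0.29 to -0.15. Most of these sets of genes that fell had low means over all arrays. The means were 3.18 to 3.38 for Armc8, 3.82 for Cpe, 3.08 for Susd5 and 3.08 to 3.32 for Slk. For Unc45a they were 4.65 and 3.28, and for Meg3 3.02 to 3.31. At such levels a steep fall can hardly show, so they do not tell whether the transcript was lost. Sets too dim to be tested changed by 0.42 (Armc8), -0.14 (Unc45a) and -0.17 (Slk). In all, limma called 19587 of the 22518 probe sets tested after Benjamini-Hochberg adjustment (8864 rose and 10723 fell), of which 4091 rose and 123 fell at least 2-fold, 3846 and 114 of them in 18 of 18 mice. The direction of the many small changes depended on the scale, since 45.3% of the calls were rises on the deposited values, 52.6% after median centring, 53.2% after quantile normalization within each preparation, 37.7% after quantile normalization of all arrays and 99.9% after spike-in centring. Among calls of at least 2-fold 97.1% were rises, against 63.2% (1307 rose and 760 fell) when all arrays were forced to the same distribution. Changes followed the signal level, with a median of -0.15 among the 12434 probe sets with a mean of at most log2 3.5, 1.43 among the 1821 between log2 5 and 7, and 0.89 among the 663 above log2 9. After spike-in centring the calls of Zfp420, Slk, Mex3a and Nrip2 ended.

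Red cell genes other than globins mostly gained signal. All 17 tested genes of the erythrocyte membrane and cytoskeleton rose (median log2 change 1.48), among them the Rh-associated glycoprotein gene Rhag (2.43 ± 0.10 (SE), n = 18), the adducin gene Add2 (2.37 ± 0.10) and the anion exchanger Slc4a1 (1.48 ± 0.07). The call of Slc4a1 rested on its brightest probe set, since the mean of all its sets changed by 0.18 with an adjusted p of 0.12. Camera placed this list above other genes (adjusted p = 2.02e-06, and adjusted p = 0.0817 with an estimated correlation). In heme synthesis 9 of 11 genes rose, among them Alad (2.41 ± 0.13), Urod (1.78 ± 0.09) and Tspo2 (1.35 ± 0.08). Alas2, the erythroid rate-limiting enzyme (-0.29 ± 0.02), and Fech (-0.17 ± 0.03), both near log2 14 in whole RNA, fell slightly. That list had a median of 0.95 (adjusted p = 0.0250, and adjusted p = 0.155 with an estimated correlation), which was 0.11 and lost its call when all arrays were quantile normalized. Of 21 other erythroid genes 17 rose, including the transcription factor genes Zfpm1 (2.52 ± 0.12) and Tal1 (1.73 ± 0.08) and the ubiquitin ligase gene Ube2o (1.69 ± 0.07). The bright genes Bpgm (-0.17), Mkrn1 (-0.14) and Isca1 (-0.13) fell together with Trim10 (-0.15). Its median was 1.13 (adjusted p = 0.000328, and adjusted p = 0.155 with an estimated correlation).

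The adult globin list itself had 7 of 7 probe sets lower, with a median of -1.03 (adjusted p = 0.000328, and adjusted p = 0.0817 with an estimated correlation). With all probe sets of a gene averaged its camera adjusted p was 0.0715. The embryonic globins split. Hbb-bh1 fell (-1.45 ± 0.09), Hba-x fell (-0.19 ± 0.04), and Hbb-y rose by 2.24 and 2.33 on a pair of probe sets in 18 of 18 mice but not on its remaining set (0.03, adjusted p = 0.744). This list had a median of -0.19, a mean of 0.20 and no call (adjusted p = 0.793).

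Markers of leukocytes and platelets were mostly higher after depletion. Among platelet and megakaryocyte genes 20 of 22 rose (median 1.12), led by the integrin gene Itgb3 (2.83 ± 0.12 (SE), n = 18), Gp5 (1.65 ± 0.07) and the von Willebrand factor gene Vwf (3.06 ± 0.14). The receptor gene P2ry12 fell (-1.59 ± 0.08). Of 16 B cell markers 15 rose (median 1.18), such as Fcmr (2.11 ± 0.07), Ighm (1.73 ± 0.07) and Spib (2.00 ± 0.09). Of 20 T cell markers 14 rose, such as Cd3d (1.89 ± 0.09), Lat (1.6 ± 0.08) and Ccr7 (1.19 ± 0.08). Cd4 (-0.30 ± 0.06), Skap1 and Trat1 fell. The list median of 0.87 was 0.35, without a call, after quantile normalization of all arrays. Neutrophil markers rose in 13 of 16 cases (median 0.80), among them Slc2a3 (1.19 ± 0.06), Anxa1 (1.65 ± 0.08) and S100a9 (1.49 ± 0.11). Of 19 monocyte and macrophage markers 15 rose (median 0.59), such as Ms4a6b (1.75 ± 0.09) and F13a1 (1.73 ± 0.09). Ctss, which rose by 0.99 ± 0.07 on the deposited scale, turned to -0.33 after quantile normalization of all arrays. The camera adjusted p was 5.94e-06 for platelet genes, 5.46e-05 for B cell genes, 0.00135 for neutrophil genes and 0.00555 for monocyte genes. Each of these 4 lists had an adjusted p = 0.155 with an estimated correlation. For T cell genes it was 0.00555 (adjusted p = 0.236 with an estimated correlation).

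NK and cytotoxic cell genes had 8 members higher and 1 lower of 14, including Gzma (1.83 ± 0.11 (SE), n = 18), Nkg7 (1.66 ± 0.11) and Ccl5 (1.49 ± 0.12), but no list call (median 0.24, adjusted p = 0.0690). Eosinophil, basophil and mast cell genes split into 3 that rose, among them Gata2 (1.76 ± 0.08) and Il6ra (1.38 ± 0.13), and 4 that fell, among them Cd200r3 (-0.21 ± 0.03), around a median of 0.00 (adjusted p = 0.793). In MHC class II 8 of 10 genes rose, such as H2-Ob (2.00 ± 0.12), H2-Aa (1.46 ± 0.11) and the invariant chain gene Cd74 (1.07 ± 0.10). The list's median of 1.11 (adjusted p = 0.0103, and adjusted p = 0.236 with an estimated correlation) was 0.10 without a call under quantile normalization of all arrays, where H2-Aa changed by 0.16 without a call and Cd74 by -0.18. In MHC class I and peptide loading 10 of 14 rose, such as Tapbp (1.76 ± 0.07), H2-K1 (1.47 ± 0.08) and H2-D1 (1.38 ± 0.08). Tap1 (-0.37 ± 0.04), Erap1 and H2-T24 fell. The list's median was 0.95 (adjusted p = 0.0159, and adjusted p = 0.155 with an estimated correlation). Interferon-stimulated genes were mixed, with 16 of 29 higher, such as Irf7 (1.85 ± 0.11) and Ifi27 (1.89 ± 0.12). Of the others 8 were lower, among them Rsad2 (-0.23 ± 0.02), and there was no list call (median 0.30, adjusted p = 0.0731). Ifit2 rose by 1.39 ± 0.09 but by 0.04, without a call, after quantile normalization of all arrays.

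Genes of the basic cell machinery rose in large numbers, as brighter probe sets did in general. With a mean between log2 5 and 7, 1648 of all 1821 tested probe sets rose (median 1.43). Above log2 9 it was 558 of 663 (median 0.89), and above log2 3.5 up to 5 it was 3838 of 6886 (median 0.33). Camera compares a list with probe sets of any level. For the lists that rose, here and above, its calls therefore do not set them apart from genes of like level. In oxidative phosphorylation 67 of 75 genes rose (median 1.40), such as the complex I genes Ndufa6 (2.35 ± 0.09 (SE), n = 18) and Ndufb6 (1.85 ± 0.07) and the ATP synthase gene Atp5pb (2.10 ± 0.08). Ndufs8 fell (-1.44 ± 0.10). Of 46 cytosolic ribosomal protein genes 43 rose (median 1.15), such as Rplp2 (2.04 ± 0.07), Rpl13a (1.86 ± 0.05) and Rps24 (1.04 ± 0.04). Rps16 fell (-1.17 ± 0.37, in 16 of 18 mice). Of 43 proteasome genes 40 rose (median 1.15), such as Psma3 (2.11 ± 0.08), Psmb5 (1.73 ± 0.07) and Psmd14 (1.61 ± 0.07). Of 29 splicing and nuclear RNA genes 26 rose (median 1.1), such as Ddx17 (1.94 ± 0.09) and Sf3b1 (1.88 ± 0.08). A Meg3 probe set fell (-2.78), while the other tested sets of that gene, near the floor, changed by -0.29 to -0.15. The median of the splicing list turned to -0.07 after quantile normalization of all arrays. The camera adjusted p was 5.77e-15 for oxidative phosphorylation, 9.71e-10 for the proteasome and 2.02e-06 for splicing, each with an adjusted p = 0.0817 with an estimated correlation. It was 2.21e-12 for ribosomal proteins (adjusted p = 0.0901 with an estimated correlation). Immediate early and stress response genes had 18 of 30 higher, such as Btg2 (2.17 ± 0.09), Hsph1 (1.93 ± 0.09) and Dusp1 (1.64 ± 0.09), and 4 lower, such as Dusp2 (-0.76 ± 0.14) and Nr4a2 (-0.63 ± 0.09). Its median of 0.43 (adjusted p = 0.00555, and adjusted p = 0.155 with an estimated correlation) was 0.06 without a call after quantile normalization of all arrays.

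Zinc finger (Zfp) genes, taken to stand for GC-rich or short-lived transcripts, mostly fell, as dim probe sets did in general. Of 195 such genes 128 fell and 41 rose, with a median of -0.15 but a mean of 0.01 and a median level of 3.37 in whole RNA (camera adjusted p = 0.00212, lower, and adjusted p = 0.350 with an estimated correlation). Of the 12434 probe sets with a mean of at most log2 3.5, 8276 fell with the same median. Large changes went both ways, as in Zfp644 (2.72 ± 0.13 (SE), n = 18), Zfp106 (2.03 ± 0.10), Zfp384 (1.87 ± 0.08) and Zfp420 (-2.35 ± 0.14). The known strain alleles had 9 genes higher, such as Alad, Wdfy1 (1.54 ± 0.07) and Trim12c (1.11 ± 0.09), and 8 lower of 19 (median 0.01, adjusted p = 0.752). Adjusted over the list alone, the counts of members that rose and fell were the same in all 22 lists. With the preset correlation 17 of the 22 lists passed, and 0 with an estimated correlation (camera in limma). Of the 17 calls 12 held after quantile normalization of all arrays, where NK genes passed in addition, and 3 held after spike-in centring (adult globins, ribosomal proteins and oxidative phosphorylation). All these groups moved together with the 3' minus 5' difference (1.04 higher in GLOBINclear RNA). Among probe sets with a mean of at least log2 5 the adult globin list alone kept its call, while the zinc finger median was 0.79.

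**Figure D2:**
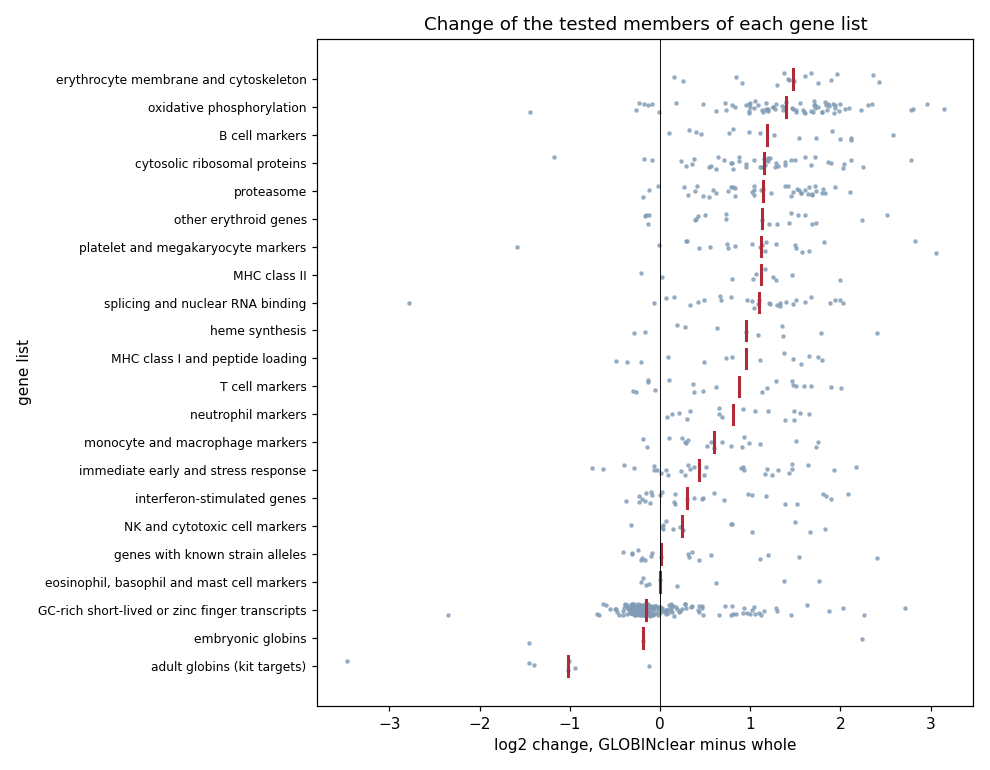
Log2 change (GLOBINclear minus whole) of each tested member of the 22 gene lists, 1 point per gene or adult globin probe set, with the list's median as a bar and the lists on the y axis. Adult globins lie at or below -0.12 with a median of -1.03, oxidative phosphorylation has a median of 1.40 and erythrocyte membrane genes 1.48. Centring on the hybridization spike-ins would move every point up by 2.08, which puts the adult globin median above 0, and quantile normalization of all arrays turns the median of the splicing list to -0.07.

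Whether depletion acted alike in all strains was asked next. Hbegf, which encodes a heparin-binding growth factor, rose from 5.81 ± 0.23 (SD, n = 3) to 7.79 ± 0.22 in C3H/HeJ, a log2 change of 1.99. It stood near 2.2 in both preparations of the other strains, with changes of -0.10 to -0.06 (limma interaction adjusted p = 1.28e-09). Sult4a1 rose by 2.70 in 129S1/ImJ and 2.95 in DBA/2J and stayed near 3 elsewhere. Gsta2, a glutathione transferase gene, rose by 1.64 in 129S1/ImJ and 1.82 in C57Bl/6J. Mlycd, the gene of malonyl-CoA decarboxylase, rose by 2.93 in DBA/2J, Ooep by 2.65 in C57Bl/6J and Rbks by 1.67 in C3H/HeJ. The strains with a rise were those with the highest means in whole RNA, as for Mlycd in DBA/2J (5.57 ± 0.79 against 2.65 to 2.70), with the smallest difference for Ooep (2.93 ± 0.13 against 2.69 to 2.71). For Rbks no strain difference was called in whole RNA (adjusted p = 0.482). In the strains without a rise these 6 genes stayed at 3.39 or below in both preparations, near the floor, where an effect of depletion can hardly show. The interaction was called for 619 probe sets (128 with a filter at log2 5), and 3271 had an unadjusted p under the threshold. Of the 619, 308 moved in the same direction in all strains, and in 311 the sign was not the same in all. Any change in sign counted, however small, as for Hbegf with -0.10 to -0.06 outside C3H/HeJ. The 311 thus do not show that depletion lowered a transcript in some strains. With the mouse as a random replicate block in place of the fixed one, 1039 were called.

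Within single strains limma called 15851 probe sets in 129S1/ImJ (7226 rose and 8625 fell), 14961 in C3H/HeJ (6470 and 8491), 14138 in C57Bl/6J (6818 and 7320), 14099 in FVB/NJ (6283 and 7816), 12499 in DBA/2J (6851 and 5648) and 10780 in A/J (5546 and 5234). Of the probe sets with a 2-fold change over all mice 99.3% moved in the same direction in all 6 strains. Some of these counts rested on single mice. Without A/J replicate 2 the A/J count was 5873, without C57Bl/6J replicate 1 the C57Bl/6J count was 9018, and without DBA/2J replicate 2 the DBA/2J count was 7359. Paired analysis mattered most for A/J, where 7139 were called with no replicate block.

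**Figure D3:**
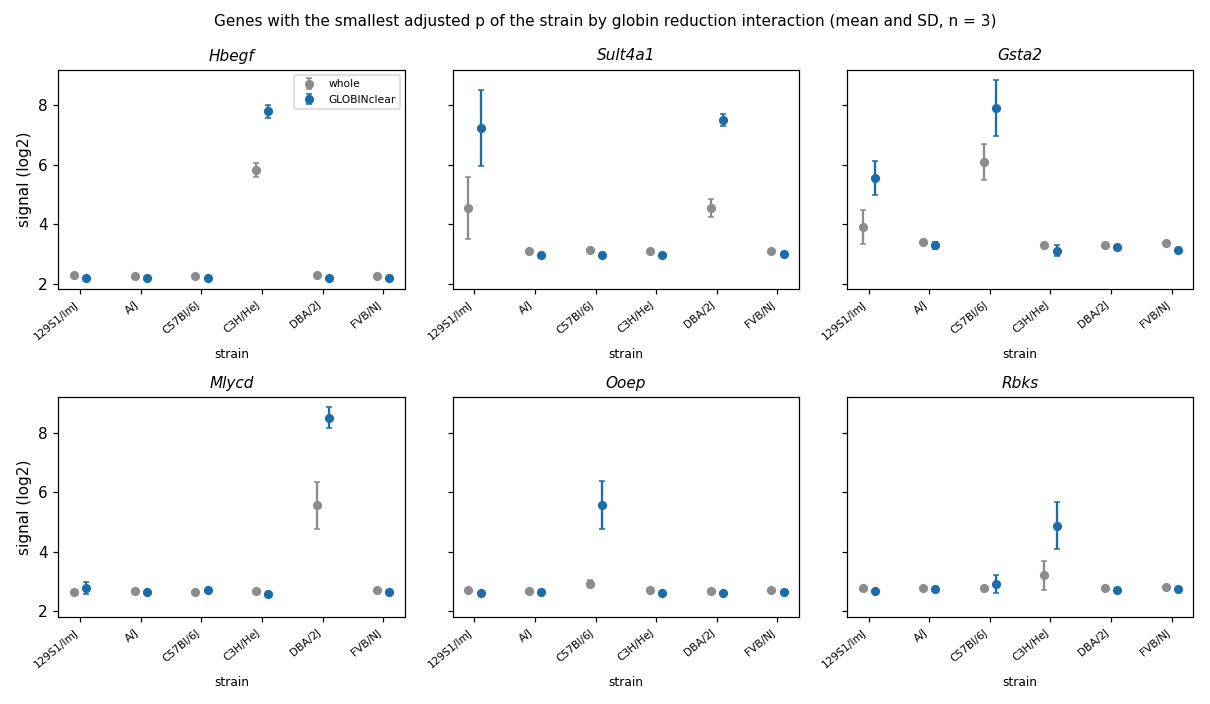
Log2 signal (mean and SD, n = 3 mice) of the 6 genes with the smallest interaction p, by strain on the x axis, in whole and GLOBINclear RNA. Hbegf in C3H/HeJ (5.81 to 7.79) and Mlycd in DBA/2J (5.57 to 8.51) rise, while the other strains stay below 3. Centring on the hybridization spike-ins would raise the GLOBINclear values by 2.08 on average relative to the whole values, which also turns the small falls of the other strains to rises.

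The strains themselves were compared in each preparation, since an aim of depletion is to see more of such differences. Platelet genes varied most among the lists, with 15 of 22 differing between strains in whole RNA, 16 in GLOBINclear RNA and 13 in both. In oxidative phosphorylation the numbers were 10, 20 and 9 of 75, among interferon-stimulated genes 3, 10 and 3 of 29, among other erythroid genes 9, 11 and 6 of 21, and among neutrophil markers 0, 5 and 0 of 16. A difference seen in whole RNA and not in GLOBINclear RNA was that of Stx1a, a syntaxin gene, at 6.12 ± 1.1 (SD, n = 3) in A/J and 6.45 ± 0.98 in DBA/2J against about 3.1 in the others, and at 3.07 to 3.48 in all strains after depletion (interaction adjusted p = 0.000161). Smim22 (3.68 in DBA/2J against 2.86 to 3.12), Tcf15 (4.71 in C3H/HeJ against 3.77 to 4.27) and Slc25a15 (3.31 in 129S1/ImJ against 2.89 to 2.95) were of the same kind. The whole RNA call of Smim22 ended with the mean of all its probe sets (adjusted p = 0.0519) and that of Slc25a15 after spike-in centring (adjusted p = 0.105). The interaction of Slc25a15 had an adjusted p of 0.188. In the opposite case were Tecpr2 (3.80 ± 0.22 in C57Bl/6J after depletion), Vps13b (4.42 ± 0.50 in A/J and 4.34 ± 0.22 in FVB/NJ), Lhpp (5.0 ± 0.26 in C57Bl/6J) and Treml4 (4.08 ± 0.31 in 129S1/ImJ and 4.12 ± 0.22 in C3H/HeJ), all of which had an interaction adjusted p of 0.000723 or below. Genes of both kinds were chosen because they passed in 1 preparation and not in the other. Their interaction p-values are therefore no independent evidence.

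Limma's F test called 973 probe sets in whole RNA and 2530 in GLOBINclear RNA, 2.60 times as many, with 772 called in both. Of the 1758 called in GLOBINclear RNA alone, 708 had an unadjusted p under the threshold in whole RNA. The difference of 1557 exceeded that of all 99 random swaps of the preparation within mice, made after the mean effect of preparation was taken out (highest 1325, permutation p = 0.01, the smallest possible). It was 220 after spike-in centring and 344 with a filter at a mean of log2 5, and it turned to -953 with array weights (7336 and 6383 called), a fit whose weights did not converge.

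Of all genes Gdpd3 separated the strains most. Its signal was 13.7 ± 0.10 (SD, n = 3) in whole RNA and 13.4 ± 0.05 in GLOBINclear RNA of 129S1/ImJ, 13.4 ± 0.05 and 12.9 ± 0.02 in FVB/NJ, and near 2.2 in the other strains. It stood 9.20 ± 0.10 (SE) above the mean of the other strains in 129S1/ImJ (limma adjusted p = 1.46e-17) and 8.72 ± 0.10 in FVB/NJ. In the others it was among the lowest genes (-4.50 in A/J, -4.48 in C57Bl/6J and DBA/2J, -4.46 in C3H/HeJ). Gdpd3 stood near the floor in these strains, so the sizes of its differences are lower bounds. The same holds for Hbegf in C3H/HeJ and Mlycd in DBA/2J below, whose other strains stood near the floor. In 129S1/ImJ Npy, the neuropeptide Y gene, was higher by 6.91 ± 0.08, and Yipf4 (-4.39 ± 0.29) and Serinc3 (-3.50 ± 0.17) were lower. Ifitm1 was higher by 2.9 ± 0.74 (adjusted p = 0.0319), a call that ended without 129S1/ImJ replicate 3 (1.20, adjusted p = 0.0939) and without the filter on signal. A/J stood out by Emb (3.92 ± 0.45), the complement inhibitor gene Cd59a (2.9 ± 0.32), Hs6st1 (2.86 ± 0.23) and low Scamp1 (-2.61 ± 0.26). C57Bl/6J did so by Ift140 (4.55 ± 0.41), Gsta2 (3.44 ± 0.23), Tspo2 (3.29 ± 0.37) and low Glrx (-4.67 ± 0.46). C3H/HeJ had high Hbegf (4.57 ± 0.05), Ppp1r21 (4.55 ± 0.33) and Redrum (3.78 ± 0.11) and low H2-K1 (-4.04 ± 0.26). Another H2-K1 set passed limma's F test over strains as well (adjusted p = 0.000166 in whole and 8.40e-06 in GLOBINclear RNA). Those with means of 5.51 (adjusted p = 0.364 and 0.185 in the same test) and 3.62 did not. DBA/2J had high Mlycd (4.37 ± 0.12), Naa16 (3.32 ± 0.15) and H2-Ea (2.64 ± 0.16) and low Edem1 (-2.59 ± 0.18). FVB/NJ had high Pck2 (2.67 ± 0.32) and Josd2 (2.64 ± 0.38) and low Ms4a4b (-4.41 ± 0.41) and H2-Eb1 (-3.51 ± 0.53). Of the list of known strain alleles, H2-Ea, an MHC class II chain, passed in both preparations (6.32 and 6.41 in DBA/2J against 3.47 to 4.29 in whole RNA of the others), as did Alad, lowest in C57Bl/6J (3.31 and 4.78) and highest in A/J (5.91 and 8.15).

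Counts against the other 5 strains were 1306 in C57Bl/6J (872 higher and 434 lower), 1301 in 129S1/ImJ (622 and 679), 846 in FVB/NJ (622 and 224), 729 in A/J (349 and 380), 482 in DBA/2J (231 and 251) and 312 in C3H/HeJ (169 and 143). They depended on single mice. The 129S1/ImJ count was 796 without 129S1/ImJ replicate 3 and 2184 without C57Bl/6J replicate 1, and the C57Bl/6J count 678 without replicate 2 of that strain. The A/J count was 446, 337 and 264 without its replicates 1, 2 and 3, and the DBA/2J count 278, 283 and 251. For C3H/HeJ it was 176 and 145 without replicates 2 and 3, and for FVB/NJ 521 and 444 without replicates 1 and 3.

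Gene lists were also compared between strains, and 57 of 132 camera tests passed with the preset correlation but 0 with an estimated one (lowest adjusted p = 0.572). Platelet genes were lower in 129S1/ImJ (median -0.69, 9 of 22 genes called lower, 18 adjusted over the list alone, adjusted p = 6.15e-13, and adjusted p = 0.572 with an estimated correlation). They were also lower in A/J (-0.41, 6 lower and 1 higher, 11 and 1 adjusted over the list alone, adjusted p = 0.000218, and adjusted p = 0.756 with an estimated correlation). They were higher in C57Bl/6J (0.74, 10 higher and 1 lower, 18 and 1 adjusted over the list alone, adjusted p = 4.42e-10). So they were in FVB/NJ (0.61, 5 higher, 16 adjusted over the list alone, adjusted p = 1.22e-11). Both had an adjusted p = 0.572 with an estimated correlation. Neutrophil genes were higher in 129S1/ImJ by a median of 1.65, which was 0.57 without replicate 3 of that strain, the array that stood apart (5 of 16 called, 13 adjusted over the list alone, adjusted p = 5.88e-10, and adjusted p = 0.691 with an estimated correlation). They were lower, with 0 members called, in A/J (-0.60, adjusted p = 0.0120), C57Bl/6J (-0.59, adjusted p = 0.00606) and FVB/NJ (-0.61, adjusted p = 0.00206), each with an adjusted p = 0.810 with an estimated correlation. Without 129S1/ImJ replicate 3 these medians were -0.27, -0.30 and -0.33, and the A/J call was lost without A/J replicate 2 (-0.49).

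B cell genes were higher in DBA/2J (0.74, 4 of 16 called, 10 adjusted over the list alone, adjusted p = 2.32e-12). So were MHC class II genes (1.21, 1 of 10 called, 8 adjusted over the list alone, adjusted p = 2.64e-12). MHC class II genes were lower in FVB/NJ (-0.78, 2 of 10 called, 6 adjusted over the list alone, adjusted p = 1.58e-07). These 3 had an adjusted p = 0.572 with an estimated correlation. In A/J MHC class II genes were lower with 0 called (-0.60, adjusted p = 0.00575, and adjusted p = 0.777 with an estimated correlation), a call lost without A/J replicate 3 (-0.28). B cell genes were lower in FVB/NJ (-0.55, 0 called, 2 adjusted over the list alone, adjusted p = 7.95e-06, and adjusted p = 0.754 with an estimated correlation). They were also lower in 129S1/ImJ (-0.43, 0 called, adjusted p = 0.00579) and A/J (-0.44, 1 called, adjusted p = 0.00606), both with an adjusted p = 0.810 with an estimated correlation. The 129S1/ImJ call was lost after spike-in centring and without its replicates 2 (-0.36) or 3 (-0.25), with -0.72 without replicate 1, and the A/J call without A/J replicate 3 (-0.14). In C57Bl/6J B cell genes were higher (0.62, 0 called, adjusted p = 0.0259, and adjusted p = 0.830 with an estimated correlation), but the median turned to -0.083 with array weights, which did not converge. That call was lost without C57Bl/6J replicates 1 (0.20) or 2 (0.50), 129S1/ImJ replicate 2 (0.61), A/J replicate 3 (0.55), C3H/HeJ replicate 2 (0.56) or FVB/NJ replicate 2 (0.58), and the median was 1.08 without C57Bl/6J replicate 3.

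Interferon-stimulated genes were lower in 129S1/ImJ (9 of 29 called lower, 9 lower and 1 higher adjusted over the list alone, median -0.08, adjusted p = 0.00206, and adjusted p = 0.702 with an estimated correlation). They were lower in FVB/NJ too (-0.11, 2 called, 7 adjusted over the list alone, adjusted p = 6.47e-06). They were higher in C57Bl/6J (5 called, 6 adjusted over the list alone, median 0.20, adjusted p = 0.000148) and C3H/HeJ (0.05, 2 called higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.000210). These 3 had an adjusted p = 0.572 with an estimated correlation. The 129S1/ImJ call was lost after spike-in centring, and its median was -0.16 without 129S1/ImJ replicate 2 and -0.04 without replicate 3. The C57Bl/6J call was lost without C57Bl/6J replicate 1 (median 0.10), and the C3H/HeJ median was 0.09 without replicate 1 of that strain. Immediate early genes were higher in 129S1/ImJ (0.21, 5 of 30 called higher and 2 lower, 7 and 2 adjusted over the list alone, adjusted p = 0.000765, and adjusted p = 0.702 with an estimated correlation), which was lost without replicate 3 of that strain (0.11). They were lower in FVB/NJ (-0.12, 0 called, adjusted p = 0.0215, and adjusted p = 0.777 with an estimated correlation), which was lost without C57Bl/6J replicate 1 (-0.090) or FVB/NJ replicates 2 (-0.14) or 3 (-0.12). Oxidative phosphorylation genes were lower in DBA/2J (-0.38, 7 of 75 called lower and 1 higher, 15 and 2 adjusted over the list alone, adjusted p = 2.33e-09, and adjusted p = 0.702 with an estimated correlation). They were higher in FVB/NJ (0.35, 11 higher and 1 lower, 15 and 3 adjusted over the list alone, adjusted p = 6.01e-06, and adjusted p = 0.756 with an estimated correlation). Without FVB/NJ replicate 2 that call was lost and the median was 0.03. They were also higher in C3H/HeJ (0.11, 2 called, 4 adjusted over the list alone, adjusted p = 3.23e-05, and adjusted p = 0.761 with an estimated correlation).

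Among red cell lists, erythrocyte membrane genes were higher in A/J (0.48, 2 of 17 called, 4 adjusted over the list alone, adjusted p = 6.98e-07, and adjusted p = 0.702 with an estimated correlation). They were also higher in C3H/HeJ (0.27, 0 called, 2 adjusted over the list alone, adjusted p = 0.000178, and adjusted p = 0.756 with an estimated correlation), with 0.46 without C3H/HeJ replicate 1 and 0.13 without replicate 3. They were lower in 129S1/ImJ (-0.74, 5 called, 7 adjusted over the list alone, adjusted p = 0.000114, and adjusted p = 0.756 with an estimated correlation), with a median of -0.43 without replicate 1 of that strain. They were also lower in C57Bl/6J (-0.22, 4 called, 6 adjusted over the list alone, adjusted p = 0.00127, and adjusted p = 0.792 with an estimated correlation). There the median ranged from -0.43 without C57Bl/6J replicate 3 to -0.06 without replicate 1. It moved over 1.5 times without 129S1/ImJ replicates 1 and 2 or FVB/NJ replicate 2 as well (-0.33, -0.15 and -0.14), and turned to 0.03 with array weights, which did not converge. Heme synthesis genes were higher in A/J (0.35, 4 of 11 called, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00252, and adjusted p = 0.754 with an estimated correlation).

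Ribosomal protein genes were higher in A/J (0.16, 3 of 46 called higher and 1 lower, 12 and 1 adjusted over the list alone, adjusted p = 2.02e-07, and adjusted p = 0.754 with an estimated correlation). They were lower in FVB/NJ (-0.10, 1 higher and 1 lower called, 1 and 2 adjusted over the list alone, adjusted p = 0.00196, and adjusted p = 0.810 with an estimated correlation), with -0.068 without C57Bl/6J replicate 1. In C57Bl/6J they were lower by a median of -0.06 (4 called, 5 adjusted over the list alone, adjusted p = 0.00928, and adjusted p = 0.810 with an estimated correlation). That median turned to 0.10 without C57Bl/6J replicate 3, lost its call without replicate 2 (-0.0082) or after spike-in centring, and was -0.20 without replicate 1. It was -0.023, -0.036 and -0.041 without 129S1/ImJ replicate 1, A/J replicate 2 and FVB/NJ replicate 2. In C3H/HeJ they were higher by 0.036 (0 called, adjusted p = 0.0241, and adjusted p = 0.830 with an estimated correlation), a call lost after spike-in centring and after quantile normalization. It turned to -0.020 without C3H/HeJ replicate 1 and -0.012 without C57Bl/6J replicate 3. The call was lost without C3H/HeJ replicate 2 (0.021), 129S1/ImJ replicate 2 (0.024), DBA/2J replicate 1 (0.016) or FVB/NJ replicate 2 (0.023). The median was 0.093, 0.057, 0.020 and 0.019 without C3H/HeJ replicate 3, C57Bl/6J replicate 1, A/J replicate 3 and FVB/NJ replicate 3.

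Of the remaining leukocyte lists, monocyte and macrophage genes were higher in 129S1/ImJ, as neutrophil genes were (0.49, 2 of 19 called, 9 adjusted over the list alone, adjusted p = 6.51e-05, and adjusted p = 0.702 with an estimated correlation), with 0.26 without replicate 3 of that strain. They were lower in A/J (-0.50, 1 called, adjusted p = 0.000528, and adjusted p = 0.754 with an estimated correlation) and FVB/NJ (-0.41, 0 called, adjusted p = 0.00606, and adjusted p = 0.761 with an estimated correlation), the latter a call lost without FVB/NJ replicate 2 (-0.32). In C3H/HeJ they were higher (0.23, 0 called, adjusted p = 0.0120, and adjusted p = 0.797 with an estimated correlation), which turned to -0.052 without C3H/HeJ replicate 1. T cell genes were higher in 129S1/ImJ (0.40, 2 of 20 called, adjusted p = 0.00485) and C57Bl/6J (0.37, 0 called, adjusted p = 0.00850). Lower medians were found in A/J (-0.50, 1 called, adjusted p = 0.0189) and FVB/NJ (-0.28, 0 called, adjusted p = 0.00606), and each of the 4 had an adjusted p = 0.810 with an estimated correlation. The 129S1/ImJ call was lost without replicate 1 of that strain (0.11), with 0.61 without replicate 3. The C57Bl/6J median turned to -0.14 without C57Bl/6J replicate 1 and was 0.64 and 0.72 without replicates 2 and 3. The A/J call was lost without A/J replicates 2 (-0.44) or 3 (-0.30), and the FVB/NJ call without FVB/NJ replicate 2 (-0.17), with -0.12 without C57Bl/6J replicate 1. In A/J and FVB/NJ the neutrophil, monocyte, T cell, B cell and MHC class II lists thus all passed as lower at the preset correlation, but not at an estimated one. Several of these calls ended when a single mouse was left out. NK genes were higher in C57Bl/6J (0.39, 2 of 14 called, 4 adjusted over the list alone, adjusted p = 0.00346, and adjusted p = 0.761 with an estimated correlation), which was lost without C57Bl/6J replicates 1 (0.29) or 2 (0.28), with 0.64 without replicate 3. In DBA/2J they were lower (-0.15, 0 called, 1 adjusted over the list alone, adjusted p = 0.00640, and adjusted p = 0.792 with an estimated correlation). MHC class I genes were lower in A/J (-0.53, 0 called, 2 adjusted over the list alone, adjusted p = 0.00156, and adjusted p = 0.702 with an estimated correlation). They were higher in 129S1/ImJ (0.28, 3 of 14 called, 3 higher and 2 lower adjusted over the list alone, adjusted p = 0.0118, and adjusted p = 0.754 with an estimated correlation), which was lost without replicate 1 of that strain (0.14), with 0.44 without replicate 3. So they were in C57Bl/6J (0.39, 3 called, 4 adjusted over the list alone, adjusted p = 0.0230, and adjusted p = 0.756 with an estimated correlation), which was lost without C57Bl/6J replicate 1 (0.012), with 0.84 without replicate 3. Eosinophil genes passed as higher in 129S1/ImJ (0.021, 3 of 9 called, adjusted p = 0.0207, and adjusted p = 0.572 with an estimated correlation), lost without 129S1/ImJ replicate 2 (0.038) or C57Bl/6J replicate 1 (0.092), with medians of 0.0095 without FVB/NJ replicate 1 to 0.18 without C3H/HeJ replicate 1.

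Other erythroid genes were higher in A/J (0.35, 1 of 21 called higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.00227), a call lost without A/J replicate 1 (0.36). In DBA/2J they were lower (-0.15, 2 called, 4 adjusted over the list alone, adjusted p = 0.00156), with -0.27 without DBA/2J replicate 3, and both had an adjusted p = 0.754 with an estimated correlation. Adult globin sets passed as higher in C3H/HeJ (0.019, 1 of 7 called, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.702 with an estimated correlation). This median turned to -0.012 without C3H/HeJ replicate 2, was 0.048 without replicate 1, and lost its call after quantile normalization (0.024 over all arrays and within each preparation). Proteasome genes were higher in C57Bl/6J (0.31, 2 of 43 called higher and 2 lower, 3 and 2 adjusted over the list alone, adjusted p = 0.00903), lost without C57Bl/6J replicate 1 (0.0099), with 0.51 without replicate 3. In A/J they were lower (-0.24, 1 called, adjusted p = 0.0146), lost without A/J replicate 3 (-0.15), and both had an adjusted p = 0.810 with an estimated correlation. In DBA/2J their median was -0.055 (0 called, adjusted p = 0.0468, and adjusted p = 0.836 with an estimated correlation). That call was lost after median centring (-0.055) and quantile normalization (-0.015 over all arrays and -0.022 within each preparation). It was also lost without either of replicates 1 and 2 of A/J, DBA/2J, FVB/NJ and 129S1/ImJ, and without replicate 1 of C3H/HeJ or C57Bl/6J. With each mouse left out in turn the median ranged from -0.10 (without DBA/2J replicate 3, call kept) to -0.0050 (without C57Bl/6J replicate 1). Splicing genes were higher in 129S1/ImJ (0.38, 1 of 29 called higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.000487, and adjusted p = 0.756 with an estimated correlation), with 0.24 without replicate 1 of that strain. Lower medians were found in FVB/NJ (-0.32, 1 called, adjusted p = 0.00102, and adjusted p = 0.761 with an estimated correlation), with -0.21 without FVB/NJ replicate 2, and in A/J (-0.25, 1 called, adjusted p = 0.0105, and adjusted p = 0.810 with an estimated correlation), lost without A/J replicate 3 (-0.19).

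Of the 57 strain list calls 36 were lost with a filter at log2 5, which left fewer probe sets, and their medians there kept their direction. Eosinophil genes in 129S1/ImJ could not be tested there. The calls lost were B cell (A/J -0.69, C57Bl/6J 0.91, FVB/NJ -1.06, 129S1/ImJ -0.88), MHC class I (A/J -0.72, C57Bl/6J 0.83, 129S1/ImJ 0.36), MHC class II (A/J -1.03), NK (C57Bl/6J 0.89), T cell (A/J -0.99, C57Bl/6J 0.65, FVB/NJ -0.32, 129S1/ImJ 0.59), adult globins (C3H/HeJ 0.16), ribosomal (C3H/HeJ 0.027, C57Bl/6J -0.077) and erythrocyte membrane (C57Bl/6J -0.12, 129S1/ImJ -0.76). The others were heme (A/J 0.25), immediate early (FVB/NJ -0.11, 129S1/ImJ 0.050), interferon (C3H/HeJ 0.30, C57Bl/6J 0.56, 129S1/ImJ -1.06), monocyte (C3H/HeJ 0.30, FVB/NJ -0.45, 129S1/ImJ 0.044), neutrophil (A/J -1.07, C57Bl/6J -0.83, FVB/NJ -1.13), other erythroid (A/J 0.36, DBA/2J -0.29), proteasome (A/J -0.19, C57Bl/6J 0.38, DBA/2J -0.094) and splicing (A/J -0.25). There NK (DBA/2J 0.054) turned. With the brightest 25% of probe sets alone 16 were lost, namely B cell (A/J -0.46, C57Bl/6J 0.64), MHC class I (129S1/ImJ 0.38), NK (C57Bl/6J 0.72, DBA/2J -0.15), T cell (A/J -0.54, C57Bl/6J 0.44), immediate early (FVB/NJ -0.23), monocyte (C3H/HeJ 0.23, FVB/NJ -0.45), neutrophil (A/J -0.72), proteasome (A/J -0.26, C57Bl/6J 0.35, DBA/2J -0.073), splicing (A/J -0.26) and eosinophil (129S1/ImJ 0.30). With the mean of all probe sets of a gene 8 were lost, namely MHC class I (C57Bl/6J 0.33, 129S1/ImJ 0.15), adult globins (C3H/HeJ 0.31), ribosomal (C3H/HeJ 0.0038, C57Bl/6J -0.013), immediate early (FVB/NJ -0.14), neutrophil (A/J -0.56) and proteasome (DBA/2J -0.054). With array weights, which did not converge, 14 were lost, namely B cell (A/J -0.27, 129S1/ImJ -0.21), NK (DBA/2J -0.041), T cell (FVB/NJ -0.11), adult globins (C3H/HeJ 0.015), ribosomal (FVB/NJ -0.072), immediate early (FVB/NJ -0.096), monocyte (C3H/HeJ 0.10, FVB/NJ -0.23), neutrophil (C57Bl/6J -0.26), proteasome (C57Bl/6J 0.018, DBA/2J -0.013), splicing (A/J -0.15) and eosinophil (129S1/ImJ 0.099), and 5 turned, namely B cell (C57Bl/6J -0.083), MHC class I (C57Bl/6J -0.037), NK (C57Bl/6J -0.073), T cell (C57Bl/6J -0.11) and erythrocyte membrane (C57Bl/6J 0.034). Without C57Bl/6J replicate 1 and 129S1/ImJ replicate 3 together 8 were lost, namely B cell (C57Bl/6J 0.16, 129S1/ImJ -0.22), NK (C57Bl/6J 0.20), immediate early (FVB/NJ -0.069), interferon (C57Bl/6J 0.082, 129S1/ImJ -0.045), proteasome (DBA/2J -0.023) and eosinophil (129S1/ImJ 0.037), and MHC class I (C57Bl/6J -0.030), T cell (C57Bl/6J -0.18) and proteasome (C57Bl/6J -0.028) turned. Spike-in centring ended 5, namely B cell (129S1/ImJ -0.60), ribosomal (C3H/HeJ 0.053, C57Bl/6J -0.11), interferon (129S1/ImJ -0.25) and other erythroid (A/J 0.50), and turned proteasome (DBA/2J 0.020) and eosinophil (129S1/ImJ -0.15).

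The spread between mice of a strain was compared last. Over all tested probe sets the median log2 ratio of the SD in GLOBINclear RNA to that in whole RNA was 0.14 (permutation p = 0.258). Its direction depended on the setting. It passed as a higher spread after quantile normalization within each preparation (0.28), after spike-in centring (0.36) and without A/J replicate 1 (0.20). It passed as a lower spread after quantile normalization of all arrays (-0.21) and with a filter at log2 5 (-0.25), and it was -0.030, without a call, when C57Bl/6J replicate 1 was left out. Among the 1377 probe sets with a mean of at least log2 7 it was -0.33, a lower spread after depletion (permutation p = 0.001, the smallest possible), which was -0.08 (permutation p = 0.287) after spike-in centring. Preparation accounted for 50.5% of the sum of squares of a probe set at the median and the mouse within its strain for 19.5%. The strain accounted for 9.56% and the strain by preparation term for 5.44%. Among probe sets with a mean of at least log2 7 the shares were 53.9% for preparation and 11.8% for the mouse. There the strain had 24.5% and the strain by preparation term 1.58%. Shares were not divided by degrees of freedom, of which mice within strains have more than strains. The strain and mouse shares can therefore not be ranked against each other.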

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

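Strain labels redistributed over mice, and preparations swapped within mice, were tests set in advance, while the 7 other tests in this part were chosen only after the result was seen. The interaction test of strain and globin depletion called 619 probe sets, which is what drew attention to it, and 128 with a filter at log2 5. The largest minus the smallest strain effect on the log2 scale was 3.09 for Sult4a1, 3.05 for Mlycd, 2.76 for Ooep, 2.09 for Hbegf, 2.06 for Gsta2 and 1.79 for Rbks. In the strains without a rise these genes stayed at 3.39 or below in both preparations, near the floor, so the differences do not show that depletion acted differently on the same transcript. Chance could be excluded for the count, since the highest of the other splits gave 18 probe sets.

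Chance could also be excluded for globin depletion over all strains (19587 against a highest other of 15459), for strain differences in whole RNA (973 against 9) and in GLOBINclear RNA (2530 against 87), and for A/J (729 against 283), C57Bl/6J (1306 against 618), C3H/HeJ (312 against 103), DBA/2J (482 against 361) and FVB/NJ (846 against 10) set against the other strains. For 129S1/ImJ it could be excluded as well, but another split gave more (1580 against 1301), so that 2 of 100 splits were as large. For depletion within a strain, with 4 splits each, the splits were too few (highest other 0 against 15851 in 129S1/ImJ, 10780 in A/J, 14138 in C57Bl/6J, 14961 in C3H/HeJ, 12499 in DBA/2J and 14099 in FVB/NJ).

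More probe sets differed between strains after depletion (2530 against 973). Kit runs that differed between strains were argued against, since among probe sets called in GLOBINclear RNA alone the strain means of both preparations correlated at a median of 0.821, against at most 0.656 in 100 shuffles of the strains. Low signal in whole RNA and the scale of the arrays cannot be told apart from a gain in detection. Among 1097 probe sets with a whole RNA mean of at least log2 7 the counts were 436 and 309, a ratio of 1.41 (1.24 to 1.70 with a mouse left out) against 2.60 over all, and the difference of counts was 220 after spike-in centring but 1717 after quantile normalization of all arrays. The strain comparison is the biological part of the design, but the counts are of probe sets. Other sets of a gene did not always differ between strains, as for H2-K1 and Gpaa1. A strain call thus holds for the signal of a probe set, and whether it reflects the amount of transcript was not tested. Why more passed was not tested further.

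Outside the globins 117 probe sets fell at least 2-fold. Loss of the gene's transcript was argued against for the 30 genes with another probe set at log2 5 or above in whole RNA, since these others changed by a median of 0.797 (bootstrap interval 0.349 to 1.11) and no other fell 2-fold in 27 of the 30, although all did in 1, Tcn2. Which probe sets counted as others was redefined after a first result, with the same outcome. Probe sets that cross-hybridize with globin or other removed sequence may account for part of the falls, as 27.4% had a suffix that marks shared probes (_x_at or _s_at) against 14.1% of all tested (Fisher's exact p = 0.000148). No biological explanation was tested, since both preparations came from the same mouse.

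The 3' minus 5' difference of beta-actin and Gapdh was higher after depletion in 18 of 18 mice. A rise shared by all transcripts through the signal scale was argued against, since the mean of this difference over the hybridization spike-ins changed by 0.000875. Single spike-ins moved in opposite directions, however. The BioB sets changed by -2.82 (3') and -2.25 (5') and the BioC sets by -2.22 (3') and -2.66 (5'). An effect of scale that differs between probe sets thus remains possible, since such shifts cancel in a mean. For the labelling reaction a shared rise was argued against by the mean of the poly-A spike-ins (-0.00647). Shortening of the sample RNA during the kit's steps, and masking of the difference by globin RNA, could each be the cause and were not tested.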

How the results depend on the processing

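Chosen only after the data were seen were the filter at log2 5, the globin sets of at least log2 8, the spread among probe sets of at least log2 7 and the pair of mice left out together. How a list call counts as held was revised after the alternatives had first been computed, and which strain lists are followed was settled after their values were seen. The 3' minus 5' difference kept its direction and call in all settings run, and so did the globin signal except after spike-in centring. On that scale the globin signal stood 0.887 higher in GLOBINclear RNA. Relative to the shift of all probe sets it was lower, but this takes off the same shift that centring added and was no test. Filters cannot change either measure, and centring cannot change the 3' minus 5' difference, so such settings were no test of them. Leaving out the mouse block or making it random changed no call other than the counts given here. For lists the random block was not tested, since camera was run there without a block. The pseudocount choice does not apply to log2 values. Signal over background limits these results, since a probe set near the floor shows a compressed change, as can a globin set near the top. Where nothing else is said, the cause was not tested.

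After quantile normalization of all arrays 1307 probe sets rose and 760 fell at least 2-fold, the interaction count was 366 and the spread ratio -0.21 (turned, passing as lower). The change in probe sets at or above log2 5 was -0.222, since all arrays then share 1 distribution. List medians were heme 0.11, T cell 0.35, MHC class II 0.10 and immediate early 0.063 (calls lost), NK 0.15 (call gained), and splicing -0.071, eosinophil -0.025 and strain alleles -0.036 (turned), as did Ctss (-0.33) and Cd74 (-0.18). Quantile normalization within each preparation gave a spread ratio of 0.28 (call gained).

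After spike-in centring, which moves all GLOBINclear values up, 22483 rose and 13 fell (22409 and 8 at least 2-fold), and the counts were 22452 in A/J, 22479 in C57Bl/6J, 22465 in C3H/HeJ, 22447 in DBA/2J and 22478 in FVB/NJ. Strain differences in GLOBINclear RNA numbered 1672 and the difference of counts was 220, with 857 in C57Bl/6J, 313 in DBA/2J and 538 in FVB/NJ against the others and a spread ratio of 0.36 (call gained). List calls lost, medians relative to the shift, were heme 0.95, erythrocyte membrane 1.48, other erythroid 1.13, T cell 0.87, B cell 1.18, neutrophil 0.80, monocyte 0.59, platelet 1.12, MHC class II 1.11, MHC class I 0.95, immediate early 0.43, proteasome 1.15, splicing 1.1 and zinc finger -0.15. Eosinophil genes in 129S1/ImJ turned to -0.15 and proteasome genes in DBA/2J to 0.020. With a correlation estimated by camera the same 14 lost their calls at the same medians, and so did adult globins -1.03, ribosomal proteins 1.15 and oxidative phosphorylation 1.40. With the mean of all probe sets of a gene adult globins had -1.37 (call lost).

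With no filter, so that more probe sets were tested, 38578 were called (28738 fell), 30490 in 129S1/ImJ, 17518 in A/J, 26029 in C57Bl/6J, 28301 in C3H/HeJ, 20473 in DBA/2J and 24680 in FVB/NJ. List medians were NK 0.15, interferon 0.17 and strain alleles 0.12 (calls gained), zinc finger -0.11 (lost) and eosinophil -0.025 (turned). With the brightest 25% alone, so that fewer were tested, 10162 were called (3119 fell), 8523 in 129S1/ImJ, 6987 in A/J, 8109 in C57Bl/6J, 8210 in C3H/HeJ, 7884 in DBA/2J and 8046 in FVB/NJ. Calls were lost for heme 0.79, other erythroid 1.13, T cell 1.16, neutrophil 1.05, monocyte 0.91, MHC class II 1.16, MHC class I 1.52 and immediate early 0.91, and embryonic globins turned to 0.39.

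With a filter at log2 5, fewer still, 3074 were called (2872 rose and 202 fell, 2128 and 58 at least 2-fold), 2817 in 129S1/ImJ, 2864 in A/J, 2789 in C57Bl/6J, 2831 in C3H/HeJ, 2930 in DBA/2J and 2824 in FVB/NJ. The interaction count was 128, strain differences in GLOBINclear RNA 1676, the difference of counts 344 and the spread ratio -0.25 (turned, passing as lower). Calls were lost for heme 1.09, erythrocyte membrane 1.55, other erythroid 1.26, T cell 1.6, B cell 2.01, neutrophil 1.49, monocyte 1.11, platelet 1.12, MHC class II 1.16, MHC class I 1.42, immediate early 1.04, ribosomal proteins 1.20, oxidative phosphorylation 1.53, proteasome 1.41 and splicing 1.3, and zinc finger genes turned to 0.79, as did NK genes in DBA/2J to 0.054.

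With no replicate block 7139 were called in A/J, and with a random block the interaction count was 1039. With array weights, which did not converge for comparisons of strains, strain differences numbered 7336 in whole and 6383 in GLOBINclear RNA, a difference of -953, and against the others 2139 in 129S1/ImJ, 2585 in A/J, 810 in C57Bl/6J, 1607 in C3H/HeJ and 2107 in DBA/2J. Medians turned for eosinophil -0.043, strain alleles -0.0082 and, in C57Bl/6J, erythrocyte membrane 0.034, B cell -0.083, NK -0.073, MHC class I -0.037 and T cell -0.11. At an adjusted p under 0.01, a stricter threshold, the counts were 5923 in A/J, 7415 in DBA/2J, 253 for the interaction, and 488 and 1310 for strains in whole and GLOBINclear RNA (difference 822). Against the others they were 579 in 129S1/ImJ, 291 in A/J, 634 in C57Bl/6J, 175 in C3H/HeJ, 261 in DBA/2J and 372 in FVB/NJ. Requiring 2-fold as well left 4214 (4091 rose and 123 fell), 4766 in 129S1/ImJ, 3905 in A/J, 4227 in C57Bl/6J, 4189 in C3H/HeJ, 4847 in DBA/2J and 4176 in FVB/NJ, and against the others 476, 250, 469, 160, 216 and 304 in the same order.

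Leaving out each mouse in turn gave depletion counts of 5873 to 11380 in A/J, 9018 to 14421 in C57Bl/6J and 7359 to 13159 in DBA/2J. Against the others the counts were 796 to 2184 in 129S1/ImJ, 264 to 995 in A/J, 678 to 1462 in C57Bl/6J, 145 to 431 in C3H/HeJ, 251 to 626 in DBA/2J and 444 to 1010 in FVB/NJ. Medians were -0.12 to 0.031 for eosinophil genes, -0.056 to 0.040 for strain alleles, -0.20 to 0.10 for ribosomal proteins in C57Bl/6J and -0.020 to 0.093 in C3H/HeJ, -0.14 to 0.72 for T cell genes in C57Bl/6J, -0.012 to 0.048 for adult globins and -0.052 to 0.33 for monocyte genes in C3H/HeJ, and the spread ratio -0.030 (without C57Bl/6J replicate 1) to 0.20 (without A/J replicate 1, call gained). Without C57Bl/6J replicate 1 and 129S1/ImJ replicate 3 together the first 2 medians were -0.13 and -0.016 and the spread ratio -0.028, T cell -0.18, MHC class I -0.030 and proteasome genes -0.028 turned in C57Bl/6J, with counts of 1154 in A/J, 582 in C3H/HeJ and 845 in DBA/2J. Eosinophil genes had -0.10 without the strain 129S1/ImJ and strain alleles -0.095 without C57Bl/6J, and calls were gained for NK genes without DBA/2J (0.30) and interferon genes without FVB/NJ (0.38).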

Other observations

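Globin probe sets differed between strains. An Hbb-b2 set stood at 8.99 in whole RNA of C57Bl/6J against 11.3 to 11.6 in the other strains, and at 5.65 against 7.68 to 8.17 after depletion. An alpha globin set stood at 15.52 in C3H/HeJ and 15.56 in FVB/NJ against 14.2 to 14.4 elsewhere in whole RNA, and at 14.6 and 14.5 against 12.5 to 12.8 after depletion. Each value is a mean of 3 mice.

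Gpaa1, which encodes a subunit of the GPI transamidase, was bright in whole RNA of A/J (9.54) and DBA/2J (9.71) and stood at 6.77 to 6.94 in the other strains. After depletion it was at 6.85 and 6.69 against 3.30 to 3.90, a fall in every strain. Another tested Gpaa1 probe set (mean 4.23) changed by 0.69. That set had no strain call (limma F test adjusted p = 0.0812 in whole and 0.281 in GLOBINclear RNA).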
